A study of Homo sapiens with 5 samples.

How the data were processed

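RNA of HepG2 cells was measured on 5 GeneChip expression arrays after labelling with a 3′ in vitro transcription kit. Per the labels' protocols, cells grown in medium with 25 mM glucose and 10% serum received siRNA by lipofection at about 50% confluence, and RNA was taken 3 to 4 days later. The groups followed the labels, with 3 arrays for LSD2 siRNA, each a different siRNA, and 2 arrays for the control siRNA. Because the labels describe the second control array as a technical replicate, the control arrays were averaged to 1 sample. Nothing in the labels says that the knockdown arrays came from separate experiments, so p-values measure only the spread between these samples, which includes differences between siRNAs and may be partly technical.

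The arrays were summarised with MAS5, per the submitters' processing notes. The deposited values were read as log2 values, since they ran from -7.05 to 7.47 on both sides of 0. The base of the logarithm is not given in the sources used here, and base 2 was assumed. In the deposited table the 5 values of each of the 30137 probe sets had a median of exactly 0, so each probe set had been centred on its own median, and the level of a gene was not in the values. The median of every array was 0.00. How the probe sets were filtered, and any scaling between arrays, is not given in the sources used here. MAS5 values of dim probe sets are noisy on a log scale, and with the levels removed most such probe sets could not be recognised. In 16 probe sets 2 or more arrays held an exactly equal value, in each case the lowest of the 5, which was read as a floor, and a single array at the floor cannot be seen this way. The signal over background was therefore unknown, and only the number of arrays could be taken as a limit on precision.

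Probe sets were named through the platform's annotation table, with symbols compared with current gene records by gene ID, and 0 symbols needed an update. Of the probe sets 24151 had 1 gene symbol, 1175 had several and 4753 had none in that table, and 58 were control probe sets. Those with 1 symbol gave 12893 genes, of which 6164 had more than 1 probe set. No genome build is named with the values, and no coordinates are given.

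The plan fixed before the data were examined assumed MAS5 signals on a linear scale. Since the levels were absent, its pseudocount, its filter on dim probe sets, its intensity trend and its choice of the brightest probe set per gene could not be applied. The mean of a gene's probe sets was used instead, all genes were kept, and the variance model had no trend. Log2 values were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with the 3 siRNAs against the averaged control. The fit had 2 residual degrees of freedom, all from the spread between siRNAs, and the lone control was assumed to vary like the knockdowns. Adjusted p-values are Benjamini-Hochberg values over all genes, with a threshold of 0.05. Gene lists were tested with camera of limma at a preset correlation of 0.01, two-sided and adjusted over the 25 lists with at least 5 measured members, and again with the correlation estimated from the residuals and with fry. The 27 lists held 744 genes, of which 556 were measured. They covered lipid and liver metabolism, histone methylation, imprinted genes, the cell cycle, stress responses and markers of other cell types. Tables and plots were made with pandas 2.3.3 and matplotlib 3.10.9 in Python 3.11.15.

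Named genes followed a rule fixed before the data were examined. It took KDM1B, the genes past the threshold or, as none passed, the 5 highest and 5 lowest by the weakest of the 3 siRNAs, up to 2 members per list by the same measure, and for each siRNA the 2 genes highest and 2 lowest against the nearest other sample. Other genes are stated to have been chosen after their values were seen.

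The fit was tested on simulated data over 12893 genes, with variances drawn from the fitted limma model. Of 50 genes made to differ by 1, 2, 3 or 4 on the log2 scale, limma called 0 at each size at the threshold and 17, 45, 45 and 50 at an unadjusted p under 0.05, with median sizes of 1.02, 2.02, 2.98 and 4.10. With the variance reduced to 0.01 of its size, 48 of 50 genes that differed by 1 were called, and 50 of 50 at each larger size, with 14 false calls. A cell cycle list shifted by -0.5 gave a camera adjusted p = 0.000229 and no other list was called. Genes were drawn independently in this simulation, while the measured cell cycle list had an estimated correlation of 0.772. The simulation therefore does not show how often camera calls unchanged lists whose members vary together.

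The array batch was read from the poly-A control probe sets and was not part of the plan. It was entered as a block with the 5 arrays separate, and each siRNA was also compared with the control array of its batch. Alternatives fixed before the data were examined were quantile normalization, centring on the median (which is no check, as the arrays already had a median of 0.00), the control arrays as separate samples, a test of log ratios against 0, a replicate block, probe sets tested one by one, each array left out in turn, the estimated correlation, fry and a 1.5-fold limit. Alternatives added after the data were examined were the batch block, the first batch alone, robust eBayes, genes whose control arrays differed by under 0.5, a choice of 1 probe set per gene by its suffix, the estimated correlation as a fixed value, and controls matched by batch.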

Results

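HepG2 is a human line from a hepatic carcinoma that keeps many functions of hepatocytes, among them the secretion of plasma proteins and lipoproteins. The cells were depleted of LSD2, a flavin-dependent demethylase of lysine 4 on histone H3 that is encoded by KDM1B. The knockdown used 3 different small interfering RNAs (siRNAs), each measured on 1 array. The control was an siRNA against GL3, a firefly luciferase sequence that human cells lack, measured on 2 arrays. The labels call the second control array a technical replicate of the first, so the control counted as 1 sample. The comparison addressed which transcripts of hepatic cells changed when LSD2 was depleted. The deposited table held 30137 probe sets, which gave values for 12893 genes. All values below are on the log2 scale and are differences from the mean of the control arrays unless another reference is named. The number of arrays limited the precision of every value.

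The transcript of the targeted gene KDM1B was lower on each of the 3 knockdown arrays. Its mean difference from the control was -1.90 ± 0.63 (SD, n = 3 siRNAs). The values were -2.60 under siRNA 1, -1.73 under siRNA 2 and -1.38 under siRNA 3, or 16.5%, 30.2% and 38.4% of the control. Both probe sets of KDM1B showed the loss, but by different amounts. For the probe set with the deeper loss the deposited values were 2.16 and 1.48 on the control arrays and -2.13, -1.12 and 0.00 under siRNAs 1, 2 and 3. For the other probe set they were 0.95 and 0.08 on the control arrays and -0.73, 0.00 and -0.43 on the knockdown arrays, and this probe set alone gave a mean difference of -0.90. The limma fit gave a standard error of 0.59 and an adjusted p = 0.9999 over all genes, with an unadjusted p of 0.0236. The difference of the second control array from the first was -0.78. Against the control array of its own array batch, described next, KDM1B stood at -2.99 and -2.12 under siRNAs 1 and 2 and at -0.99 under siRNA 3, and with the batch as a block the difference was -1.88.

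Bacterial poly-A transcripts, which are added to the RNA before labelling, separated the 5 arrays into 2 batches that cut across the groups. Over 24 such probe sets, the median difference from control array 1 was 0.04 for siRNA 1 and 0.07 for siRNA 2. It was -1.45 for control array 2 and -1.39 for siRNA 3. In 22 of the 24 probe sets both of these arrays read below the other 3. The hybridisation controls, added after labelling, differed less, with medians over 18 probe sets of -0.33 for control array 2 and -0.26 for siRNA 3. The first batch thus held control array 1 with siRNAs 1 and 2, and the second held control array 2 with siRNA 3. Ratios of 3′ to 5′ probe sets, a measure of RNA integrity, differed from control array 1 by between -0.14 and 0.07 for ACTB and between -0.20 and -0.05 for GAPDH.

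**Figure D1:**
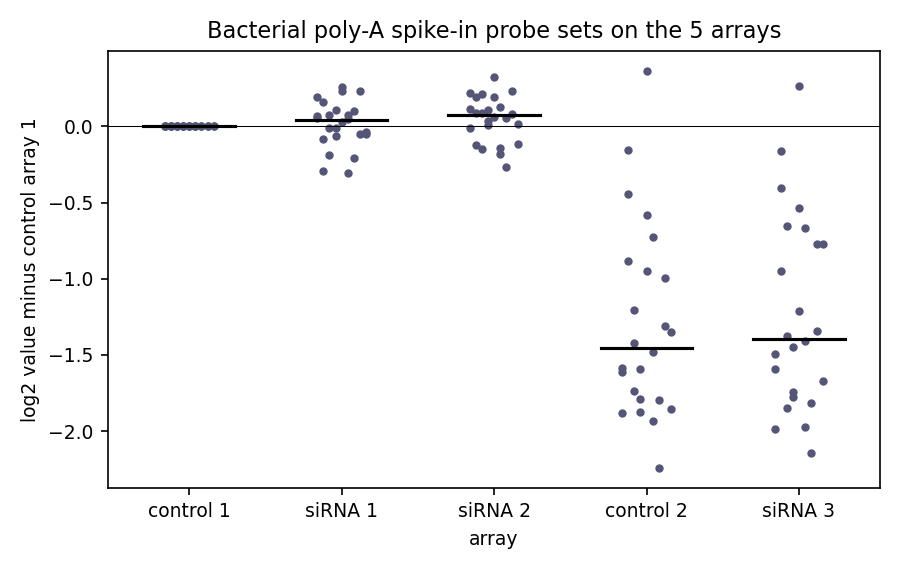
Deposited log2 values of the 24 poly-A spike-in probe sets on each of the 5 arrays, as differences from control array 1; dots are probe sets and the horizontal line is the median of an array. The medians of control array 2 and siRNA 3 lie at -1.45 and -1.39, those of siRNAs 1 and 2 at 0.04 and 0.07.

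Among single genes, the widest differences shared by the 3 siRNAs were in transcripts measured by 1 probe set each. UPK3A, which encodes a uroplakin of the urothelial plaque, stood at 4.10 ± 0.52 (SD, n = 3 siRNAs), and the integrin subunit gene ITGB8 at 3.79 or more. The uncharacterised LOC105376944 stood at 4.21 ± 0.36 and the pseudogene NUDT16L2P at 4.04 ± 0.38. KCNMB1, a potassium channel subunit gene, stood at 3.15 ± 0.06, but its control arrays differed by -3.91, and against the control array of its own batch it stood at 1.15, 1.26 and 5.08. On the lower side were PTPRZ1, a receptor tyrosine phosphatase gene, at -4.09 or lower, the antisense transcript MAMDC2-AS1 at -3.89 ± 0.69 and the chemokine gene PF4V1 at -3.77 or lower. SLC25A29, a mitochondrial carrier gene, stood at -3.24 ± 0.50 and LOC101929255 at -3.77 ± 1.17. The values of ITGB8, PTPRZ1 and PF4V1 are bounds, since both control arrays for ITGB8, siRNAs 1 and 2 for PTPRZ1 and siRNAs 1 and 3 for PF4V1 held exactly equal values at the lowest of the 5 arrays, as at a floor. None of these 10 genes passed the test. In limma, 0 of the 12893 genes reached an adjusted p under 0.05, and the lowest adjusted p = 0.9999. At an unadjusted p under 0.05 there were 218 genes, 172 higher and 46 lower, where chance alone gives 645. With the array batch as a block limma again called 0 genes, with 498 at an unadjusted p under 0.05 and a lowest adjusted p = 0.382. In data simulated with variances drawn from the fitted limma model, limma called 0 of 50 genes made to differ by 4 on the log2 scale. Under that model a count of 0 did not exclude effects of that size. Unchanged arrays drawn from it shared 280 genes 2-fold lower under all 3 siRNAs, against 42 observed, so the model may overstate the spread.

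**Figure D2:**
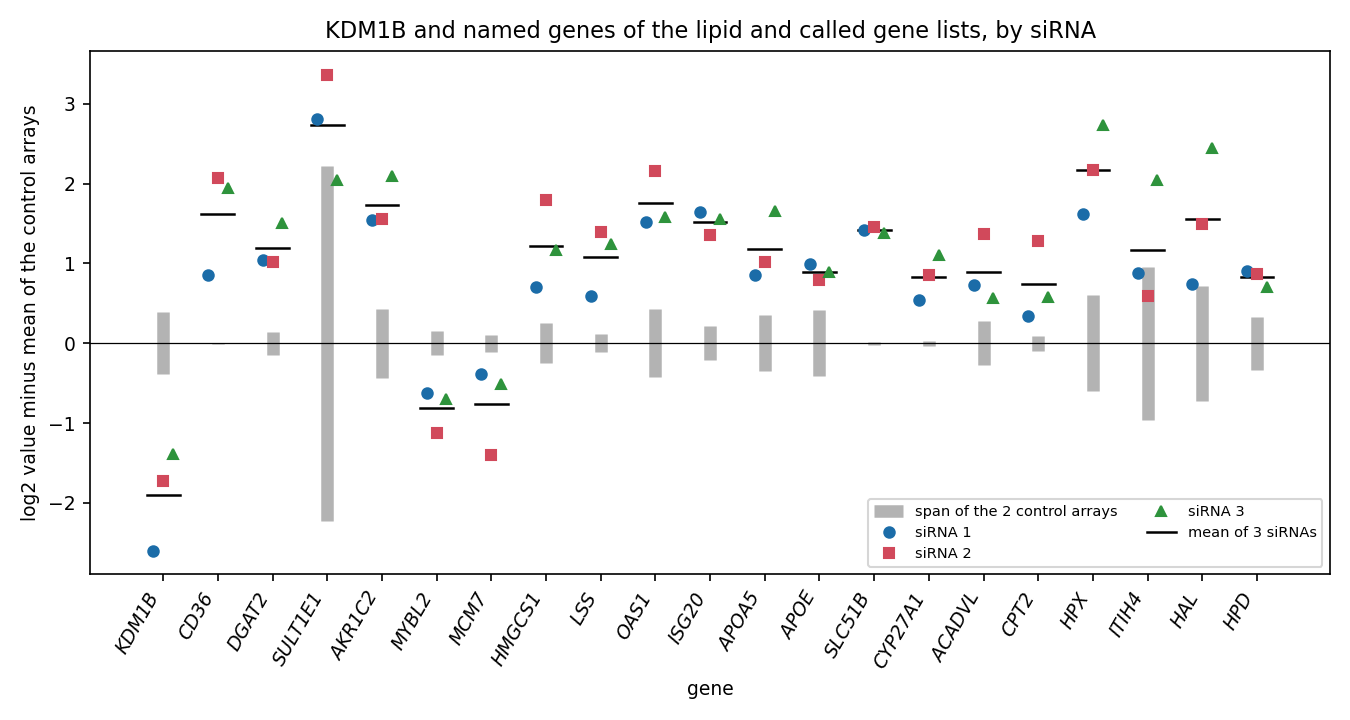
Log2 value minus the mean of the control arrays for KDM1B, CD36, DGAT2 and named members of the called gene lists; circles, squares and triangles are siRNAs 1, 2 and 3, the short line is their mean and the grey bar is the span of the 2 control arrays. KDM1B lies at -1.90, SLC51B at 1.42 with its siRNAs between 1.39 and 1.46, and SULT1E1 at 2.74 with a difference of 4.44 between its control arrays.

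Of 25 gene lists fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, 9 were called, 8 of them higher under LSD2 siRNA and 1 lower. No member of any list passed on its own: limma called 0 members over all genes tested and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 3 members in the drug metabolism list, 3 in the interferon list and at most 1 in each other list. With the correlation between genes estimated from the residuals, camera tests with 2 degrees of freedom, and 0 of the 9 calls held, with a lowest adjusted p = 0.703 over all 25 lists. A test that small says little about whether a call is stable. With each list's estimate entered as a fixed value, which keeps the degrees of freedom, drug metabolism stayed called (camera adjusted p = 1.36e-07) and the other 8 lists did not. The fry test called 0 lists too, with an adjusted p = 0.917 for direction and an adjusted p = 0.999 for change in either direction, in each list alike. Of all genes, 17.9% were higher under all 3 siRNAs and 18.2% lower.

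Genes of drug metabolism rose as a group. The median over 24 measured members was 0.79, with 0.60, 0.97 and 0.73 under siRNAs 1, 2 and 3 (camera adjusted p = 2.7e-08, and adjusted p = 0.703 with an estimated correlation). Under all 3 siRNAs 12 members were higher and 1 was lower, CYP2A6, a member named after its values were seen, which without control array 1 turned to a mean of 0.13. AKR1C2, an aldo-keto reductase that acts on steroids and xenobiotics, stood at 1.73 ± 0.31 (SD, n = 3 siRNAs). The oestrogen sulfotransferase gene SULT1E1 stood at 2.74 ± 0.66, but its control arrays differed by 4.44. Its mean was 0.52 without control array 1 and 4.96 without control array 2, and against the control of its batch siRNA 3 read -0.18. Among genes whose control arrays differed by under 0.5 the median was 0.25 (camera adjusted p = 0.0274). With the array batch as a block the list had a camera adjusted p = 1.33e-07, and within batches its medians were 0.49 and 0.90 under siRNAs 1 and 2 and 0.66 under siRNA 3.

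Genes of cholesterol synthesis and of bile acid handling rose as groups. The cholesterol list had a median of 0.53 over 21 members, with 0.09, 0.92 and 0.46 under siRNAs 1, 2 and 3 (camera adjusted p = 8.4e-05, and adjusted p = 0.721 with an estimated correlation). HMGCS1, the cytosolic synthase ahead of HMG-CoA reductase, stood at 1.22 ± 0.54 (SD, n = 3 siRNAs), and LSS, the lanosterol synthase gene, at 1.08 ± 0.42. In this list 11 members were higher under all 3 siRNAs and 1 was lower, the sterol reductase and lamin receptor gene LBR, named after its values were seen, which without control array 2 was lower under siRNA 2 alone, at -0.62. The bile acid list had a median of 0.70 over 13 members, with 0.19, 0.93 and 0.78 (camera adjusted p = 0.000317, and adjusted p = 0.721 with an estimated correlation), and 7 members were higher and 0 lower under all 3. SLC51B, a subunit of the transporter that exports bile acids across the basolateral membrane, stood at 1.41, 1.46 and 1.39 under siRNAs 1, 2 and 3, with control arrays 0.04 apart. CYP27A1, the sterol 27-hydroxylase gene, stood at 0.83 ± 0.28. With the batch as a block the camera adjusted p = 1.7e-05 for cholesterol synthesis and 0.00011 for bile acids. The cholesterol median was 0.83 without siRNA 1 and 0.30 without siRNA 2. Within batches the medians were 0.28, 1.05 and 0.41 for cholesterol synthesis and 0.31, 0.93 and 0.98 for bile acids under siRNAs 1, 2 and 3.

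Genes of lipoproteins and of fatty acid oxidation rose as groups as well. The list of apolipoproteins and lipoprotein assembly had a median of 0.53 over 18 members, with 0.34, 0.60 and 0.80 under siRNAs 1, 2 and 3 (camera adjusted p = 0.000266, and adjusted p = 0.721 with an estimated correlation). In it 7 members were higher under all 3 siRNAs and 0 lower. APOE stood at 0.89 ± 0.10 (SD, n = 3 siRNAs), or 0.48 without control array 2, and APOA5, which takes part in the clearance of triglyceride-rich lipoproteins, at 1.18 ± 0.42. The list of fatty acid oxidation and ketogenesis had a median of 0.39 over 28 members, with 0.10, 0.49 and 0.56 (camera adjusted p = 0.00057, and adjusted p = 0.721 with an estimated correlation). There 14 members were higher under all 3 siRNAs and 1 was lower, ACAD9, named after its values were seen. The very long chain acyl-CoA dehydrogenase gene ACADVL stood at 0.89 ± 0.42, and CPT2, the carnitine palmitoyltransferase gene of the inner mitochondrial membrane, at 0.74 ± 0.49 (0.46 without siRNA 2). With the batch as a block the camera adjusted p = 9.24e-05 for lipoproteins and 3.56e-05 for oxidation. Within batches the medians were 0.04, 0.51 and 0.99 for lipoproteins and 0.18, 0.57 and 0.51 for oxidation under siRNAs 1, 2 and 3. Without siRNA 3 both calls ended, with a median of 0.21 (camera adjusted p = 0.0582) for lipoproteins, where the value shrank, and of 0.37 (0.0999) for oxidation, where it was about as large. The lipoprotein call also ended in the first array batch alone, at 0.23 (camera adjusted p = 0.102), and among genes whose control arrays differed by under 0.5, at 0.18 (0.0762).

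Plasma protein genes rose as a group on average but moved apart between the siRNAs. Over 29 members the median was 0.50, with -0.49 under siRNA 1, 0.65 under siRNA 2 and 1.16 under siRNA 3 (camera adjusted p = 0.00142, and adjusted p = 0.735 with an estimated correlation). In 18 of the 29 the value was below the control under siRNA 1 and above it under the other two. Albumin (ALB) stood at -2.02, 3.03 and 2.69 under siRNAs 1, 2 and 3 and the fibrinogen chain gene FGB at -3.02, 0.57 and 2.03, both named after their values were seen. HPX, which encodes the haem-binding protein hemopexin, was among 5 members higher under all 3 siRNAs, at 2.18 ± 0.56 (SD, n = 3 siRNAs), as was ITIH4 at 1.17 ± 0.77 (0.73 without siRNA 3). For HPX the control arrays differed by -1.20, and without control array 2 it stood at 1.02, 1.57 and 2.14 under siRNAs 1, 2 and 3. The control arrays differed by 1.91 for ITIH4, and without control array 1 it stood at -0.08, -0.36 and 1.09 under siRNAs 1, 2 and 3. The others, named after their values were seen, were SERPINA1, SERPINC1 and ORM1, and without control array 2 SERPINA1 stood at -0.05 under siRNA 1. With the batch as a block the camera adjusted p = 1.7e-05, and within batches the medians were -0.40, 1.09 and 0.98. The call ended with a median of 0.33 without siRNA 2 (camera adjusted p = 0.0618), 0.10 without siRNA 3 (0.352), 0.31 without control array 1 (0.137) and 0.38 in the first array batch alone (0.0761), and the median was 0.99 without siRNA 1.

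Genes of the urea cycle and amino acid catabolism had the smallest called rise. The median was 0.18 over 26 members, with -0.07, 0.26 and 0.42 under siRNAs 1, 2 and 3 (camera adjusted p = 0.0372, and adjusted p = 0.721 with an estimated correlation). Under all 3 siRNAs 7 members were higher, among them HPD, a tyrosine breakdown enzyme gene, at 0.83 ± 0.10 (SD, n = 3 siRNAs) and the histidase gene HAL at 1.56 ± 0.85. The control arrays differed by 1.44 for HAL, and without control array 1 it stood at 0.02, 0.78 and 1.73 under siRNAs 1, 2 and 3, while HPD stood at 0.49 without control array 2. The 3 that were lower under all 3, named after their values were seen, were CBS, CTH and BCKDHB, and without control array 1 CBS and BCKDHB read 0.08 and 0.07 under siRNA 2. With the batch as a block the camera adjusted p = 0.00296, and within batches the medians were -0.04, 0.28 and 0.28. The call ended with a median of 0.17 without siRNA 2 (camera adjusted p = 0.157), 0.12 without siRNA 3 (0.352), 0.18 without control array 1 (0.221) and 0.25 in the first array batch alone (0.102). It also ended at 0.11 among genes whose control arrays differed by under 0.5 (camera adjusted p = 0.0762) and at 0.17 with 1 probe set per gene chosen by suffix (0.151). The median was 0.40 without siRNA 1 and 0.29 without control array 2, where the list stayed called.

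Interferon-stimulated genes rose as a group, while genes of the cell cycle and DNA replication fell. The interferon list had a median of 0.38 over 28 members, with 0.13, 0.62 and 0.44 under siRNAs 1, 2 and 3 (camera adjusted p = 0.000216, and adjusted p = 0.721 with an estimated correlation). OAS1, which makes the oligoadenylates that activate RNase L, stood at 1.75 ± 0.35 (SD, n = 3 siRNAs) and the exonuclease gene ISG20 at 1.52 ± 0.15. Under all 3 siRNAs 12 members were higher and 1 was lower, the membrane protein gene IFITM1, at -1.96, -1.51 and -1.04, named after its values were seen. The cell cycle list had a median of -0.50 over 44 members, and the fall was carried by siRNA 2, with medians of -0.10, -1.20 and -0.05 under siRNAs 1, 2 and 3 (camera adjusted p = 1.3e-05, and adjusted p = 0.735 with an estimated correlation). In it 17 members were lower under all 3 siRNAs and 0 higher. MYBL2, a transcription factor gene of proliferating cells, stood at -0.81 ± 0.27 and MCM7, a subunit gene of the replicative helicase, at -0.77 ± 0.55 (-0.45 without siRNA 2). Without siRNA 2 the cell cycle call ended at a median of -0.16 (camera adjusted p = 0.433). The interferon median was 0.24 without siRNA 2, 0.64 without control array 1, 0.24 without control array 2 and 0.23 in the first array batch alone. With the batch as a block the camera adjusted p = 7.14e-05 for the interferon list and 6.33e-05 for the cell cycle list. Within batches the medians were 0.08, 0.45 and 0.69 for the interferon list and -0.15, -1.27 and -0.04 for the cell cycle list under siRNAs 1, 2 and 3.

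**Figure D3:**
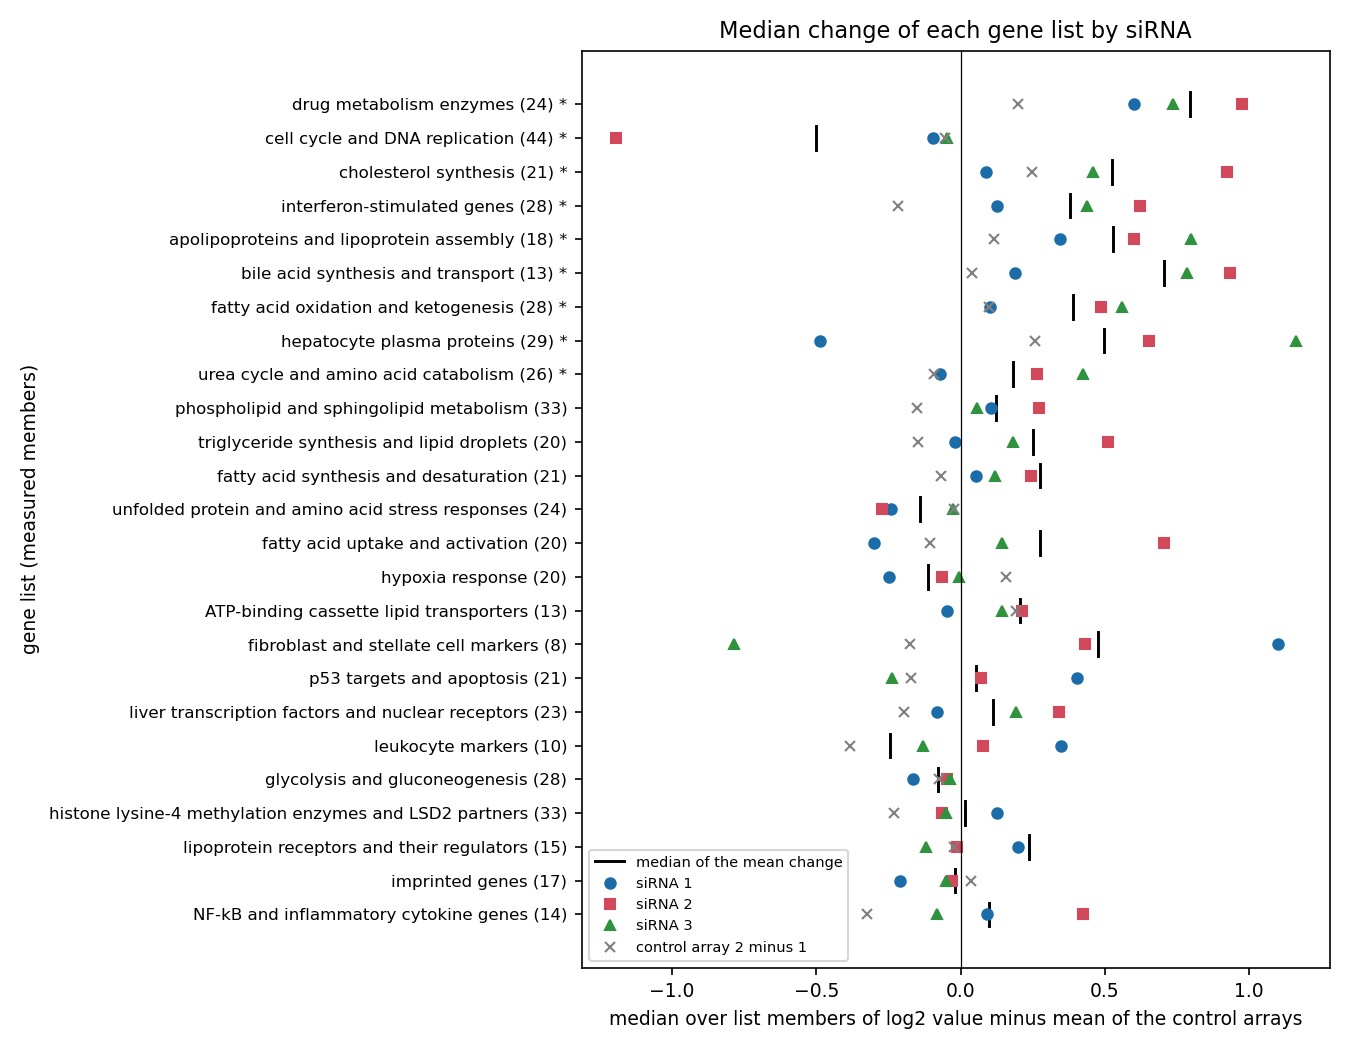
Median over the measured members of each of 25 gene lists of the log2 value minus the mean of the control arrays; circles, squares and triangles are siRNAs 1, 2 and 3, the black tick is the median of the mean difference, the cross is control array 2 minus control array 1, and an asterisk marks the 9 lists called by camera. Drug metabolism lies at 0.60, 0.97 and 0.73, while plasma proteins lie at -0.49, 0.65 and 1.16 and the cell cycle at -0.10, -1.20 and -0.05.

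Other lipid lists were not called, although single members stood apart in all 3 siRNAs. CD36, which encodes a fatty acid translocase, stood at 0.85, 2.07 and 1.95 under siRNAs 1, 2 and 3, with control arrays 0.02 apart. FABP3, a fatty acid binding protein gene, stood at 1.11 ± 0.52 (SD, n = 3 siRNAs). The list of fatty acid uptake and activation that holds both had a median of 0.27 over 20 members (camera adjusted p = 0.23, and adjusted p = 0.803 with an estimated correlation), and was called without siRNA 1 (0.0192) and with probe sets tested one by one (0.00691). DGAT2, which completes triglyceride synthesis, stood at 1.19 ± 0.27 and AGPAT2, which acts earlier in the same path, at 0.84 ± 0.10. Their list of triglyceride synthesis and lipid droplets had a median of 0.25 over 20 members (camera adjusted p = 0.116, and adjusted p = 0.721 with an estimated correlation), and was called without siRNA 1 (0.0194) and among genes whose control arrays differed by under 0.5 (0.0227). The phospholipid and sphingolipid list, with CERS2 at 0.70 ± 0.11 and PLA2G12B at 1.16 ± 0.68, had a median of 0.12 over 33 members (camera adjusted p = 0.116, and adjusted p = 0.721 with an estimated correlation) and was called among genes whose control arrays differed by under 0.5 (0.00206). Fatty acid synthesis had a median of 0.27 over 21 members (camera adjusted p = 0.155), with ACSS2 at 0.82 ± 0.57 (0.50 without siRNA 2) and MID1IP1 at 0.93 ± 0.35, and MID1IP1 read -1.01, -0.31 and 2.54 against the controls of its own batches. The lipid transporters of the ATP-binding cassette family had a median of 0.21 over 13 members (camera adjusted p = 0.415), with ABCA1, a cholesterol exporter gene, at 0.96 ± 0.29 (0.56 without control array 1) and ABCG2 at 0.98 ± 0.94 (0.44 without siRNA 1). Lipoprotein receptors had a median of 0.24 over 15 members (camera adjusted p = 0.736), with LRP2 at 0.66 ± 0.20. MYLIP, whose product degrades the LDL receptor, stood at -0.51 ± 0.13 (-0.32 without control array 2). Its 5 probe sets ran from -0.96 to 0.05 under siRNA 1 and from -1.84 to -0.09 under siRNA 3.

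The remaining lists of regulators and stress responses were not called. ASNS, the asparagine synthetase gene and a target of the amino acid response, stood at -1.20, -1.30 and -1.25 under siRNAs 1, 2 and 3, and ATF4, a transcription factor gene of that response, at -0.78 ± 0.44 (SD, n = 3 siRNAs). Their list of unfolded protein and amino acid stress responses had a median of -0.14 over 24 members (camera adjusted p = 0.2, and adjusted p = 0.721 with an estimated correlation), and was called among genes whose control arrays differed by under 0.5 (0.0414). The glucose transporter gene SLC2A1 stood at -0.93 ± 0.22 and the enolase gene ENO2 at -0.95 ± 0.48, in a list of glycolysis and gluconeogenesis with a median of -0.08 over 28 members (camera adjusted p = 0.733). Enzymes of histone H3 lysine 4 methylation and partners of LSD2 had a median of 0.02 and a mean of -0.03 over 33 members (camera adjusted p = 0.736, direction lower). In it NSD3 stood at -0.50 ± 0.21 and SMYD3 at 0.32 ± 0.11 (0.18 without control array 1). The 6 probe sets of NSD3 disagreed, running from -1.54 to 0.75 under siRNA 1 and from -1.53 to 0.19 under siRNA 2. Imprinted genes had a median of -0.02 over 17 members (camera adjusted p = 0.836), with SLC67A1, formerly SLC22A18, at 0.92 ± 0.03 and IGF2R at 0.39 ± 0.11. Liver transcription factors and nuclear receptors had a median of 0.11 over 23 members (camera adjusted p = 0.729), with HNF4G at -0.70 ± 0.38 (-0.38 without control array 2, and -0.01 under siRNA 3) and THRB at 0.49 ± 0.16. The hypoxia list, with STC2 at -0.69 ± 0.27 and MXI1 at -0.55 ± 0.25 (-0.36 without control array 1), had a median of -0.11 over 20 members (camera adjusted p = 0.385). The p53 list, with GADD45B at -0.52 ± 0.08 and RRM2B at 0.77 ± 0.61 (0.43 without siRNA 1), had a median of 0.05 over 21 members (camera adjusted p = 0.489), and without control array 1 RRM2B stood at 0.92 under siRNA 1 and -0.23 under siRNA 3. The 3 probe sets of GADD45B ran from -0.93 to -0.06 under siRNA 1 and from -0.82 to -0.12 under siRNA 3. The inflammatory list, with IL32 at 1.18 ± 0.76 and LTB at -0.13 ± 0.04, had a median of 0.10 over 14 members (camera adjusted p = 0.847), and without control array 2 IL32 stood at 0.89, 0.94 and -0.40 and LTB at a mean of -0.07. The 2 probe sets of LTB read 0.10 and -0.28 under siRNA 3.

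Markers of other cell types gave no called list. Fibroblast markers had a median of 0.48 over 8 members (camera adjusted p = 0.462), with 1.10, 0.43 and -0.79 under siRNAs 1, 2 and 3. Leukocyte markers had a median of -0.24 and a mean of 0.13 over 10 members (camera adjusted p = 0.733, direction higher). Among their members DCN stood at 1.03 ± 0.52 (SD, n = 3 siRNAs), POSTN at 0.49 ± 0.18, CD14 at 1.61 ± 0.74 and TYROBP at 1.55 ± 0.27. The 2 probe sets of DCN disagreed, at 0.13, -1.02 and 0.02 under siRNAs 1, 2 and 3 for one and at 2.07, 1.98 and 2.99 for the other, whose control arrays differed by -1.50. The control arrays differed by -3.53 for POSTN and -5.37 for TYROBP, and against the first control array both were lower under siRNAs 1 and 2, at -1.37 and -1.39 for POSTN and at -0.83 and -1.34 for TYROBP. Endothelial markers and markers of cervical and kidney epithelial lines had 4 measured members each, too few to test, with medians of -0.16 and 0.05, and SFN of the latter stood at 0.54 ± 0.44, or -0.29 under siRNA 3 without control array 2.

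The 3 siRNAs differed in which genes they moved by 2-fold or more, a count that has no test with 1 array per siRNA. Under siRNA 1 the organic anion transporter gene SLCO1B3 stood at 5.10, against -1.53 and -0.44 under siRNAs 2 and 3, and the proteoglycan gene GPC1 at 3.62, while the homeobox gene HOXB7 stood at -5.33 and the interferon-stimulated helicase gene DDX60 at -4.72. Under siRNA 2 the Wnt antagonist gene DKK4 stood at 5.70 and the acyl-CoA synthetase gene ACSM2A at 5.72, with SCGB2A2 at -4.94 and LOC101928933 at -4.81. Under siRNA 3 MYCT1 stood at 3.44 and the arginase gene ARG1 at 3.36, with POU4F2 at -5.29 and CORO2B at -4.81. For ARG1, GPC1, CORO2B and ACSM2A the control arrays themselves differed by 3.65, 2.20, -2.29 and -1.97. Genes 2-fold higher and lower numbered 813 and 797 under siRNA 1, 1058 and 959 under siRNA 2, and 766 and 718 under siRNA 3. Between the control arrays, 485 genes were 2-fold higher and 888 lower on the second.

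Under all 3 siRNAs 149 genes were at least 2-fold higher and 42 at least 2-fold lower. Among those named above, CD36 was not in the higher set, since siRNA 1 gave 0.85, and AKR1C2, OAS1, ISG20, SLC51B, HPX and DGAT2 were. Also in it were UPK3A, ITGB8, LOC105376944, NUDT16L2P, KCNMB1, SULT1E1 and the leukocyte markers CD14 and TYROBP. The control arrays differed by -3.91 for KCNMB1, 4.44 for SULT1E1, -5.37 for TYROBP and -1.20 for HPX. Without control array 2 DGAT2 stood at 0.90 and 0.87 under siRNAs 1 and 2. Without control array 1 CD14 stood at 0.54 and 0.87 under siRNAs 1 and 3. Independent lists of these sizes would share 3.96 and 3.30 genes. All 3 comparisons used the same control, which adds shared values, and unchanged arrays simulated against 1 control shared 281 and 280 genes, or 128 and 127 where the control had 0.5 of the variance. The observed higher count lay between the simulated values and the lower count below both. Both simulations also gave larger covariances than those observed, given below, so they put more shared spread into the values than the data hold. They therefore cannot tell how much of the excess over independent lists comes from the shared control. Against the control array of their own batch the siRNAs shared 73 and 46 genes. No unchanged arrays were simulated for that setting, so what a control shared only in part would give is not known. The siRNAs shared 328 higher genes without control array 1 and 93 lower genes without control array 2. Across genes, which are not independent replicates, the covariance was 0.191 between siRNAs 1 and 2, 0.11 between 1 and 3, and 0.18 between 2 and 3. The simulated covariances were 0.56, 0.641 and 0.575, or 0.262, 0.26 and 0.269 with the smaller control variance. The correlations were 0.299, 0.19 and 0.288, against 0.335, 0.333 and 0.341 in that simulation. Against the control array of their own batch, which siRNAs 1 and 2 share and siRNA 3 does not, the covariances were 0.287, 0.0139 and 0.072 and the correlations 0.391, 0.0206 and 0.0981.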

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

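The batch block, the first batch alone, robust eBayes, the filter on control arrays, the choice of probe set by suffix, the estimated correlation as a fixed value and the controls matched by batch were chosen after the results were seen. The count of 0 genes past the threshold in limma held under every alternative run, with between 86 and 1506 genes at an unadjusted p under 0.05 against 218 (1506 where log ratios were tested against 0, which leaves out the spread of the control). KDM1B stayed lower under every alternative run, between -0.90 with 1 probe set chosen by suffix and -2.90 with probe sets one by one. For the gene lists, 9 were called, and between 5 (without siRNA 3) and 11 (without siRNA 1) when each array was left out in turn, including 6 without siRNA 2. The first array batch alone gave 6. The estimated correlation gave 0 on 2 degrees of freedom, the estimate as a fixed value 1 (drug metabolism), fry for direction 0 and fry for change either way 0. Drug metabolism, cholesterol synthesis, bile acid and interferon lists stayed called in each alternative of the camera test at the preset correlation, but not at 1 size, with medians between 0.25 and 0.87, 0.30 and 0.83, 0.58 and 0.76, and 0.23 and 0.64. Over the 9 called lists and these alternatives, 117 list results kept direction and call and 18 kept only the direction. Over the other lists 209 results kept both, 8 became called and 22 turned direction without a call. The direction camera gives can differ from the sign of the median, as for leukocyte markers. Among values of named genes, 1108 stayed in direction and on their side of the threshold, and 24 changed sign without a call. No gene passed in any fit, so the side of the threshold could not tell stable values from others. Most of these genes were picked for a direction shared by all 3 siRNAs, so leaving out an siRNA could not turn their mean. The arrays sharing a replicate number were not paired: deviations correlated at 0.101 for number 1 and -0.0469 for number 2. With a replicate block 8 lists were called, 6 of them among the 9, with 0 genes, and KDM1B at -2.16. Replicate number 3 has no control array, so this block left siRNA 3 out of the comparison. Its sizes of change are therefore those without siRNA 3, where KDM1B also stood at -2.16. The lists lost were fatty acid oxidation at a median of 0.37 (camera adjusted p = 0.0595), plasma proteins at 0.10 (0.356) and the urea cycle at 0.12 (0.223). Those gained were fatty acid uptake (camera adjusted p = 0.0458) and phospholipids (0.0377). The lipoprotein list stayed called, but its median fell from 0.53 to 0.21.

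Genes 2-fold higher under all 3 siRNAs numbered 149, and 203 to 328 with either control array left out, 25 among genes whose control arrays differed by under 0.5, 73 with controls matched by batch and 370 at a 1.5-fold limit. Those lower numbered 42, and 69 after quantile normalization, 58 to 93 with either control array left out, 18 under the filter on control arrays and 159 at 1.5-fold. Together they numbered 191, and 296 to 386, 43, 119 and 529 under the same settings (control left out, filter, controls matched by batch, 1.5-fold). The filter left 8861 genes. The higher counts at 1.5-fold follow from the limit, and for the filter and the others the cause was not tested. Not run, because the levels are absent from the values, were the 2 pseudocounts, both filters on dim probe sets and the robust fit with an intensity trend. The mean of probe sets and eBayes without a trend became the main choices. A random block for the control RNA (duplicateCorrelation) could not be fitted, since 5 arrays of 4 samples are too few for its estimate, and leaving out an siRNA gives no count over 3. Signal over background, which limits arrays, was unknown.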

Other observations

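The gene families below, and the tests of array batch, of list members varying together, of knockdown depth, of growth for siRNAs 2 and 3 separately and of low-side noise, were chosen after the results were seen. Of 14 gene families tested with camera of limma at the preset correlation, 6 were called. Aldo-keto reductases, which reduce steroids, aldehydes and ketones, rose as a group, with a median of 1.24 over 9 members and 0.61, 1.33 and 1.45 under siRNAs 1, 2 and 3 (camera adjusted p = 1.97e-07, and adjusted p = 0.39 with an estimated correlation). Under all 3 siRNAs 7 of the 9 were higher and 0 lower, among them AKR1E2 at 2.21 ± 0.72 (SD, n = 3 siRNAs) and AKR1B10 at 1.33 ± 0.72. The control arrays differed by 3.39 for AKR1E2, and without control array 1 it stood at -0.31, 1.02 and 0.84 under siRNAs 1, 2 and 3. Members already in a list above numbered 4, with AKR1C1, AKR1C2 and AKR1C3 in drug metabolism and AKR1D1 in the bile acid list. Both lists had been called higher before the family was chosen, so its test partly reuses their values. Proteasome subunit genes had a median of 0.16 over 33 members and 0.03, 0.08 and 0.34 under siRNAs 1, 2 and 3, with 12 higher and 0 lower under all 3 (camera adjusted p = 0.033, and adjusted p = 0.827 with an estimated correlation). PSMD3 stood at 0.55 ± 0.17 and PSMC4 at 0.46 ± 0.11, or 0.22 and 0.24 without control array 2.

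Cytosolic ribosomal protein genes had a median of -0.17 over 58 members and -0.27, -0.27 and -0.01 under siRNAs 1, 2 and 3, with 25 lower and 0 higher under all 3 siRNAs (camera adjusted p = 0.00136, and adjusted p = 0.827 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetase genes had a median of -0.32 over 15 members and -0.33, -0.35 and -0.13 under siRNAs 1, 2 and 3, with 7 lower and 0 higher (camera adjusted p = 0.0277, and adjusted p = 0.773 with an estimated correlation), CARS1 standing at -0.65 ± 0.37 (SD, n = 3 siRNAs) and AARS1 at -0.50 ± 0.21. Claudins and cadherins had a median of 0.53 over 19 members, with 0.29, 0.48 and -0.03 under siRNAs 1, 2 and 3 (camera adjusted p = 0.00974, and adjusted p = 0.81 with an estimated correlation). Of these 6 were higher under all 3 siRNAs and 3 lower, CDH2, CDH22 and CLDN11. CLDN11 stood at -1.70 ± 0.59, with a control difference of 0.43. CDH2 and CDH22 stood at -0.11 and -0.34, but their control arrays differed by more, at -0.19 and -0.46. Among the 6 higher, CDH1 stood at 3.06 ± 0.50, with a control difference of -0.33. The control arrays differed by -3.07 for CLDN23 and -2.43 for CLDN14, which were also among them. HLA genes with B2M and CD74 had a median of 0.22 over 13 members, with 0.23, 0.71 and 0.18 (camera adjusted p = 0.0155, and adjusted p = 0.81 with an estimated correlation), 7 of them higher under all 3 siRNAs and 1 lower, HLA-DPA2. Among the 7, HLA-DPB2 and HLA-DPB1 stood at 1.58 and 1.30, but their control arrays differed by more, at 3.60 and -3.66. The 6 directions were the same after quantile normalization, and with the array batch as a block the camera adjusted p lay between 1.79e-06 and 0.0463. Mitochondrial ribosomal proteins (0.863), the respiratory chain (0.548), heat shock proteins (0.412), histones (0.33), metallothioneins (0.482), zinc finger genes (0.548), olfactory receptors (0.578) and glutathione S-transferases (0.44), each with its camera adjusted p, were not called.

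Of the 9 gene lists called at the preset correlation of 0.01, 8 may owe their calls to members that vary together from array to array. The median of their estimated correlations was 0.267, and all 8 calls ended with the estimates as fixed values. These estimates too rest on 2 degrees of freedom. With 1 array per siRNA they cannot separate differences between cultures from differences between siRNAs. For drug metabolism the estimate was 0.015 and the call held, but an estimate on 2 degrees of freedom does not bound the correlation, so this stays open. The array batch as the whole cause of the directions is argued against, since all 9 lists kept direction and call with the batch as a block. The split along the batch called 2 lists. The block fit used the preset correlation and took the control arrays as separate samples, so its calls carry those limits. In the first batch alone, where the batch cannot act, the list medians kept their direction. The lipoprotein, plasma protein and urea cycle calls ended there. Of the 10 splits of the 5 arrays into 2 and 3, 2 called at least 9 lists, the real split with 9 and 1 other with 11, which set siRNAs 2 and 3 against the rest, and with 10 splits no share under 0.05 can be reached. An effect of LSD2 loss stays open beside shared variation between arrays.

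Plasma protein genes lay lower under siRNA 1 and higher under siRNAs 2 and 3. Array batch is argued against, since siRNAs 1 and 2 share a batch and differed by a list median of 1.18 (95% bootstrap interval over genes, which treats them as independent and leaves out the spread between cultures, 0.60 to 1.67). Under siRNA 1, which had the deepest KDM1B loss, the list median was -0.488 (-0.63 to -0.09), against 0.65 and 1.16 under siRNAs 2 and 3. On these arrays the list thus did not rise with the depth of KDM1B loss. A graded response to LSD2 loss stays open beyond them. The siRNA 1 median came from 1 array and from genes with an estimated correlation of 0.687. Growth state was tested through the cell cycle list, whose median under siRNA 1 exceeded the mean of siRNAs 2 and 3 by 0.525, a mixture of a difference of 1.27 from siRNA 2 (1.266, interval 0.97 to 1.44) and of 0.028 from siRNA 3 (-0.07 to 0.15). A difference in proliferation thus remains a candidate for the gap between siRNAs 1 and 2, where both lists differed. Between siRNAs 1 and 3 the plasma protein gap was wider, with a list median of 1.55 (1.12 to 2.22), while the cell cycle list hardly differed. On these arrays the siRNA 3 gap thus did not run with the cell cycle list. Whether this holds beyond them stays open, since 1 array per siRNA and genes with an estimated correlation of 0.772 give no spread between cultures. Off-target effects of single siRNAs and other differences between cultures were not tested.

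More genes were 2-fold higher than 2-fold lower under all 3 siRNAs, 149 against 42. In 9 of 9 other splits of the arrays into 2 and 3 the group of 3 also had more genes higher than lower. The excess varied, from 272 against 63 when control array 2 and siRNA 3 were the pair to 177 against 172 when siRNAs 2 and 3 were. A candidate explanation is low-side noise of MAS5 signals, in which a low reading on an array of the pair lowers its mean. The excess of higher genes therefore gives no sign of the direction of an effect of LSD2 loss, which stays open for each gene.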
